A study of Mus musculus with 15 samples.

How the data were processed

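The values used were the deposited log2 signals of 45101 probe sets on 15 Affymetrix mouse genome arrays, made with RMA per the submitters' processing notes. RMA corrects the background, quantile normalizes the arrays and summarizes the probes of each probe set as a log2 signal. The settings and version of RMA, the dates on which the arrays were hybridized and the number of amplification rounds are not given in the sources used here. The deposited arrays did not share a distribution, with lower quartiles of 3.897 to 4.294 and upper quartiles of 8.07 to 8.457. Arrays normalized before the probes are summarized need not share quartiles after it. The quartiles therefore do not tell whether these 15 arrays were normalized together, which the sources do not state. The table was used as deposited, with no further scaling, and every value column belonged to a described sample. Values ranged on a log2 scale in every array, so no transformation was applied.

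Probe sets were named from the probe table supplied for this platform. Of the 45101 probe sets, 34958 carried exactly 1 gene symbol, 932 carried several, and 9211 carried none. Probe sets with several or no symbols were left out of all gene counts and were tested apart, with the 51 controls among them counted on their own. For each gene the probe set with the highest mean over all 15 arrays stood for the gene, which gave 18194 genes, 9012 of them with more than 1 probe set. No filter on dim genes was applied. A gene table on the GRCm38.p6 assembly served for names and for the order of genes along the chromosomes.

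The 15 arrays were fitted together with 4 group means in limma 3.58.1 (lmFit, contrasts.fit and eBayes with default settings) under R 4.3.3. Contrasts were each mutant against wild type, the mean of the 3 mutants against wild type, and each pair of mutants. P-values were adjusted by the method of Benjamini and Hochberg over the 18194 genes of each contrast, and a gene passed at an adjusted p of 0.05. Each array held RNA pooled from 5 to 10 mice, so the p-values measure the spread between pools and not between mice. The probe set choice, the test, the threshold, the gene lists, the rule for named genes and 12 alternative settings besides leaving out each array were written down before the data were examined.

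Genes were named by a rule. Against wild type these were the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose mutant and wild-type arrays did not overlap, and between mutants the 5 largest each way. The 3 targeted genes and members of the gene lists were also named. Gene lists, 34 in number, were written from general knowledge of endothelial, retinal and blood cell biology: 20 for pathways or states and 14 for cell types. Each list was tested with camera at the preset correlation of 0.01, with the p-values of 34 lists and 4 contrasts against wild type (136 tests) adjusted together, and those of the 3 contrasts between mutants adjusted together. Beside each preset result stood camera with a correlation estimated from the data and the rotation test fry. The number of members past the threshold was counted once with the adjustment over all genes and once with the adjustment over the list alone.

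Overlap between mutants was compared with the product of the 2 numbers of called genes divided by the number of genes. Because all mutants shared the same 6 wild-type arrays, correlations of fold changes were compared with 50 simulations of unchanged groups and with 20 splits of the wild-type arrays into 3 and 3. Regroupings of the arrays that ignored the genotype were run through the same fit: all 84 splits of 9 arrays, all 10 splits of 6 arrays, and 100 drawn regroupings of all 15.

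The alternative settings were quantile normalization again, centring each array on its median, only genes above the median gene, the mean of all probe sets of a gene, each probe set on its own, no probe sets ending in _x_at or _s_at, eBayes with trend and robust, array weights, only the groups compared, a 2-fold minimum change, the replicate number as a block, and the mean of the rod markers as a covariate. Each of the 15 arrays was also left out in turn. The estimation of the array weights (limma default) stopped before it converged. Added after the values were seen were fits with array weights estimated gene by gene, with arrays matched by their spike controls and sex genes (as a block, with gene lists adjusted over the contrasts it could fit, or by duplicateCorrelation), without the 3 arrays that stood apart, with Xist and Eif2s3y as covariates, with the macrophage marker mean as a covariate, and with the gap between 3′ and 5′ control signals as a covariate. Tests of 27 gene families by name (Fisher's exact test, both directions, 54 tests adjusted together) were also chosen after the values were seen.

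The fit was tested on simulated data made with the spread of the real arrays. With 100 genes changed by 2-fold and 100 by 4-fold, 49% to 76% and 86% to 97% were recovered over the 7 contrasts, none with the wrong sign, among 7 to 15 false calls. Of 2 shifted gene lists both were called, and no unshifted list was. Genes varied independently in these simulations, so they cannot show how often lists of correlated genes are called falsely. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.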

Results

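Gene expression was measured in endothelial cells purified from adult mouse retina with beads carrying an antibody to PECAM. There were 3 pools from mice lacking the receptor Frizzled4 (Fz4 KO), 3 from mice lacking the coreceptor Lrp5 (Lrp5 KO), 3 from mice lacking the secreted ligand Norrin (Norrin KO) and 6 from wild-type mice, each pool from 5 to 10 animals on 1 array. The background was C57Bl6 and 129 mixed. The labels give both sexes for the pools, which the sex-linked genes below do not bear out for every pool. With 3 arrays per mutant the number of arrays limits the precision of every fold change.

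The first component of the 15 arrays held 43.2% of the variance and set the 9 mutant arrays apart from the 6 wild-type arrays. Mutant and wild-type arrays correlated at 0.911 to 0.974, arrays of the same group at 0.962 to 0.992. Lrp5 KO 1 stood away from the rest on the second component (17.8%, at 77.4), with wild type 4 and Lrp5 KO 3 next (34.0 and 29.2). Lrp5 KO 1 and wild type 4 also deviated together: after the spike controls and sex genes matched Fz4 KO 1 to 3 with wild type 1 to 3 and Lrp5 KO 1 to 3 with wild type 4 to 6, the deviations of matched arrays correlated at 0.276 to 0.653, each highest with its match. Wild-type deviations were taken there from the mean of each 3 arrays. Taken from the mean of all 6, Fz4 KO 2 correlated higher with wild type 4 (0.251) than with its match (0.0601). The labels name no such batches, and the Norrin KO arrays had no match. On Norrin KO 1 the actin control signal at the 3′ end exceeded that at the 5′ end by 2.92, and the gap was 1.05 to 2.92 in Norrin KO against 0.558 to 1.04 on the other 12 arrays. Sex-linked genes also moved with the groups: all 3 Norrin KO arrays had Xist near background and the Y gene Eif2s3y high, and Xist was −5.18 below wild type in Norrin KO, while Xist was high on all Fz4 KO arrays, and Lrp5 KO and wild type held arrays of both kinds. By these signals all 3 Norrin KO pools looked male. Fz4 KO 3, with Xist at 11.882 and Eif2s3y at 3.253, looked female, against the label of both sexes.

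**Figure D1:**
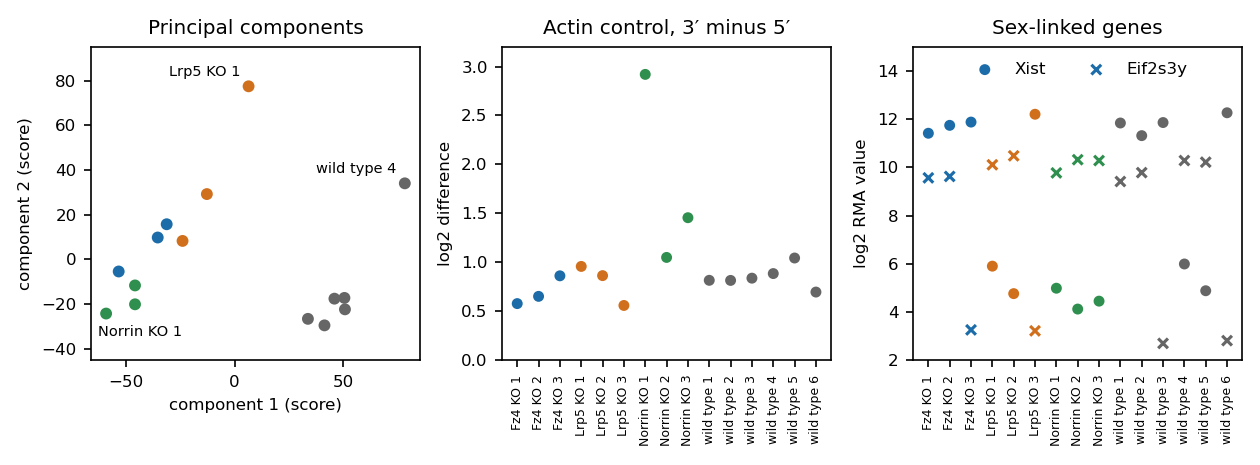
Position of each array on components 1 and 2, the 3′ minus 5′ gap of the actin control (log2), and the log2 signals of Xist (circles) and Eif2s3y (crosses), coloured by group. The mutants lie apart from wild type on component 1 (43.2%), and the gap reaches 2.92 on Norrin KO 1.

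The targeted genes were looked at first because they check the labels. Fzd4, the Norrin receptor of the endothelium, was 4.22 ± 0.30 (SD, n = 3) in Fz4 KO against 12.09 ± 0.20 (n = 6) in wild type, a fall of 7.87 on the log2 scale (adjusted p = 3.1e-13) to a signal near background, which sets the size of the fall. Its other probe sets fell by 4.94 and 1.84. Lrp5, the coreceptor, was 4.91 ± 0.45 in Lrp5 KO against 7.69 ± 0.27, a fall of 2.78 on the log2 scale to a signal near background. Ndp, which encodes Norrin and is made by Müller glia rather than by endothelium, was 4.13 ± 0.24 in Norrin KO and 4.44 ± 0.19 in wild type (log2 −0.31, adjusted p = 0.250), near background in all groups, so it checks nothing about the Norrin KO label. Among the other receptor components, Fzd4 was lower in Norrin KO by 0.44 (adjusted p = 0.0489, a call that ended with any of 10 arrays left out, adjusted p = 0.177 without Norrin KO 1) while its other 2 probe sets were at +0.23 and +0.13 and did not pass. Lrp6 was −0.52 in Fz4 KO and −0.58 in Lrp5 KO, and Tspan12, a tetraspanin that amplifies Norrin signalling, did not pass (+0.35 over the mutants). The list of 5 receptor genes holds the deleted Fzd4 and Lrp5, so its call over the mutants was fixed by the knockouts and says nothing more (camera adjusted p = 0.0356, adjusted p = 0.199 with an estimated correlation).

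The first question was what the loss of Norrin signalling, at any of its 3 components, left behind in adult retinal endothelium. The 10 genes that rose most include Plvap and Aqp1 of non-barrier capillaries and Esm1 and Kcne3 of tip cells, and 4 of the 10 that fell most are carriers. Transporters of the blood-retina barrier fell and tip cell genes rose as lists, with the preset and with an estimated correlation. By the preset alone targets of beta-catenin fell and the lists of basement membrane and the cell cycle rose (adjusted p = 0.204, 0.518 and 0.104 with an estimated correlation). The list of pan-endothelial genes did not pass, with Pecam1, the antigen used for the purification, at +0.07.

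Over the mean of the mutants Plvap, which forms the diaphragms of fenestrae and is silenced in barrier vessels, rose by 7.10 ± 0.18 (SE, n = 9 against 6), from 5.34 ± 0.53 (SD, n = 6) to more than 12 in each mutant. Gpihbp1 (+7.01), the capillary anchor of lipoprotein lipase, Btnl9 (+7.0), a butyrophilin of peripheral endothelium, and Col15a1 (+6.93), a collagen beside the basement membrane, rose nearly as far. Further down the order came Esm1 (+6.82), a proteoglycan of tip cells, Aqp1 (+6.55), the water channel of non-barrier capillaries, Adam12 (+6.18), a metalloprotease, and Cd300lg (+5.94), a receptor of fenestrated and venular endothelium. Inhbb (+5.84), an activin subunit, and Kcne3 (+5.34), a potassium channel subunit of tip cells, completed the 10 largest rises. The 10 largest falls were Slc38a5 (−7.31), a glutamine transporter, Slco1c1 (−6.10), the carrier of thyroid hormone, Car4 (−6.07), a carbonic anhydrase of capillary surfaces, Far2 (−5.78), a fatty acyl reductase, Slc19a3 (−5.66), a thiamine carrier, Slc22a8 (−5.62), an organic anion carrier, Pglyrp1 (−5.22), a peptidoglycan binder of brain endothelium, Islr2 (−4.72), a leucine-rich repeat protein, Car5a (−4.51), a mitochondrial carbonic anhydrase, and Degs2 (−4.45), a sphingolipid enzyme. On all 9 mutant arrays each of these genes lay beyond all 6 wild-type arrays. All 10 rising genes but Inhbb lay below the array medians (5.885 to 6.038) in wild type, Gpihbp1, Btnl9, Col15a1, Esm1, Adam12, Cd300lg and Kcne3 below 5, as did Slc38a5, Far2, Car4 and Car5a in the mutants. Near background the array limits the size of a change, and so the order of these genes.

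**Figure D2:**
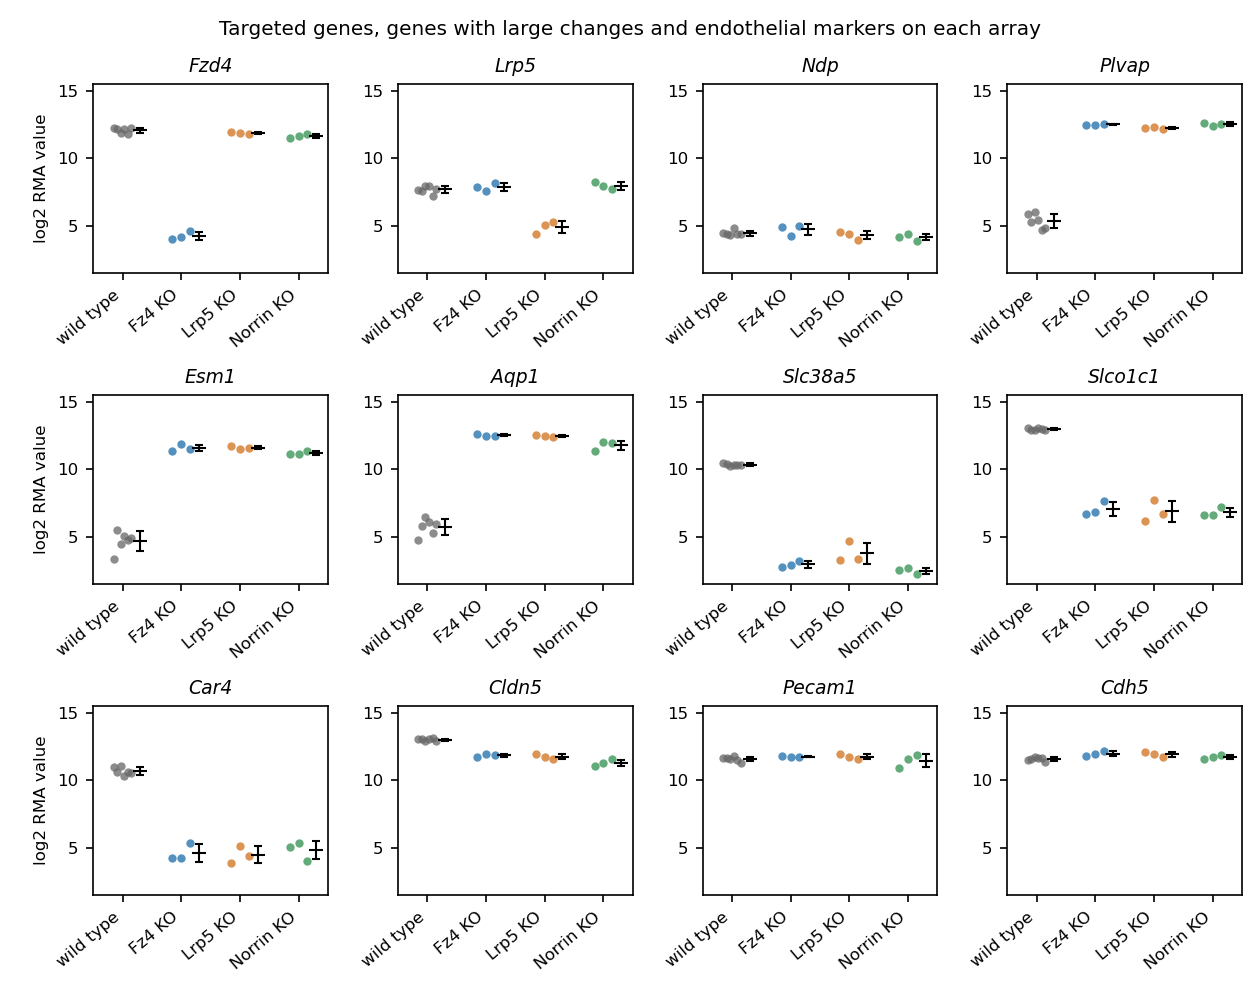
Log2 signal of 12 genes on each array by group, with bars for mean ± SD (n = 3 per mutant, n = 6 wild type). Plvap is 5.34 ± 0.53 in wild type and 12.53 ± 0.05 in Fz4 KO, Slc38a5 10.35 ± 0.10 and 2.92 ± 0.24, and Pecam1 11.59 ± 0.17 and 11.77 ± 0.06.

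Transporters of the blood-retina barrier fell without exception. All 21 measured passed over the mean of the mutants, by all genes and adjusted over the list alone, with a median of −1.79 (camera adjusted p = 2.8e-30, adjusted p = 0.00053 with an estimated correlation). Besides the carriers above, Lrp8 (−4.12), a receptor for apolipoprotein E, Mfsd2a (−4.07), the omega-3 lipid carrier that also restrains transcytosis, and Slc38a3 (−2.94), a glutamine carrier, fell far, while Slc3a2 (−0.35), the common heavy chain of amino acid carriers, and Slc2a1 (−0.59), the glucose transporter, fell least. The drug pump Abcb1a fell by 1.62. The list fell in each mutant: 20 of 21 members in Fz4 KO (21 adjusted over the list alone, median −1.98, camera adjusted p = 1.1e-30), 20 in Lrp5 KO (21, median −1.74, adjusted p = 2.9e-32) and 21 in Norrin KO (21, median −1.90, adjusted p = 1.5e-27). By mutant these were adjusted p = 0.00053, 0.00053 and 0.000629 with an estimated correlation.

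Junction genes moved both ways, though less so after centring the arrays. Over the mean of the mutants 5 of 17 fell and 3 rose (7 and 3 adjusted over the list alone, 8 and 1 after centring). The list did not pass (median −0.23, camera adjusted p = 0.0612). Ocln (−3.77), the occludin of tight junctions, and Lsr (−3.48), which marks tricellular contacts, fell most. The other probe set of Lsr was at −0.07 and did not pass. Cldn5 (−1.38), the main claudin of barrier vessels, and Tjp1 (−0.70), its scaffold, followed. Jam3 (+1.46) rose, and Cdh5 (+0.29), the cadherin of all endothelium, rose slightly. The list passed camera in Fz4 KO (4 down and 2 up, 6 and 3 over the list alone, 7 and 1 after centring, adjusted p = 0.0497) and in Norrin KO (5 down and 2 up, 6 and 3, 7 and 1 after centring, adjusted p = 0.0356). With an estimated correlation these were adjusted p = 0.290 and 0.262. It did not pass in Lrp5 KO (4 down and 1 up, 4 and 3, 3 and 2 after centring, adjusted p = 0.155). The Norrin KO call ended without wild type 3 (adjusted p = 0.0585) and with the 3′ to 5′ gap as a covariate (adjusted p = 0.0514). The list mean changed little, from −0.55 to −0.54 and −0.48. The Fz4 KO call ended without any 1 of 9 arrays, Fz4 KO 1 or 2, Lrp5 KO 1 or 2, Norrin KO 2 or wild type 1 to 4 (adjusted p = 0.0521 to 0.1). Norrin KO 1, with its long 3′ to 5′ gap, belongs to the second group.

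Fenestrae and caveolae, 9 genes measured, did not pass camera as a list (4 up and 3 down, 5 and 3 over the list alone, median +0.23, camera adjusted p = 0.160). By mutant camera gave adjusted p = 0.142, 0.0907 and 0.226 in Fz4, Lrp5 and Norrin KO. Plvap dominated the list. The rotation test fry, past which 73 of 136 tests went, gave adjusted p = 2.7e-07 for it in Fz4 KO. Cavin3 (+1.26) and Ehd4 (+0.83), a caveolar coat protein and a membrane-shaping ATPase, rose, whereas the coat proteins Cavin2 (−0.95) and Cavin1 (−0.42) and the caveolin Cav2 (−0.26) fell. Cav1 (+0.23), the core protein of caveolae, did not pass.

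Tip cell genes rose as a list. Of 20 measured, 16 rose and 2 fell (17 and 2 over the list alone), with a median of +1.14 (camera adjusted p = 3.1e-13, adjusted p = 0.00617 with an estimated correlation). After Esm1 and Kcne3 came Apln (+4.95), the apelin peptide of sprouting vessels, Ramp3 (+3.91), which pairs with the adrenomedullin receptor, Nid2 (+2.35), Trp53i11 (+2.19), Lamb1 (+2.18) and Angpt2 (+2.01), the Tie2 antagonist of remodelling vessels. Pdgfb (−0.53), which recruits pericytes, and Adm (−0.46), adrenomedullin, did not do what the list name says and fell, and Cd34 (+0.03) did not pass. Counts were 17 up and 0 down in Fz4 KO (17 and 2 over the list alone, median +1.42, adjusted p = 4.9e-15), 13 and 1 in Lrp5 KO (15 and 2, +1.09, adjusted p = 7.9e-15) and 16 and 1 in Norrin KO (16 and 1, +1.13, adjusted p = 1.4e-09). With an estimated correlation these were adjusted p = 0.00442, 0.00442 and 0.0194.

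Target genes of beta-catenin fell in part. Over the mutants 8 of 15 fell and 3 rose (8 and 3 over the list alone, mean −0.69, camera adjusted p = 0.0148, adjusted p = 0.204 with an estimated correlation). Tnfrsf19 (−3.92), a receptor of the TNF family, Axin2 (−2.64), the feedback inhibitor, Apcdd1 (−2.12), a Wnt antagonist of retinal vessels, Notum (−1.72), which inactivates Wnt ligands, and Lef1 (−1.13), a transcription factor of the pathway, fell in all 3 mutants. Myc (+1.98) and Ccnd1 (+1.20), which growth signals also drive, and Dkk2 (+1.13) rose, and Lgr5, Rnf43, Bambi and Wif1 did not pass. The list fell in Fz4 KO (8 down and 3 up, 8 and 3 over the list alone, adjusted p = 0.00991) and Lrp5 KO (8 and 2, 8 and 3, adjusted p = 0.0123), with adjusted p = 0.199 and 0.203 with an estimated correlation. In Norrin KO, the group with the weakest 5′ control signals, it passed narrowly (7 and 3, 7 and 3, adjusted p = 0.0497, adjusted p = 0.290 with an estimated correlation) and no longer without any 1 of 7 arrays. These were Lrp5 KO 2 or 3, Norrin KO 1 or 2 and wild type 2, 3 or 6 (adjusted p = 0.05 to 0.0713). Of the SoxF factors, 3 genes, Sox17 fell (−0.38) and Sox7 and Sox18 did not pass, so the list did not pass in any contrast (adjusted p = 0.823 over the mutants).

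**Figure D3:**
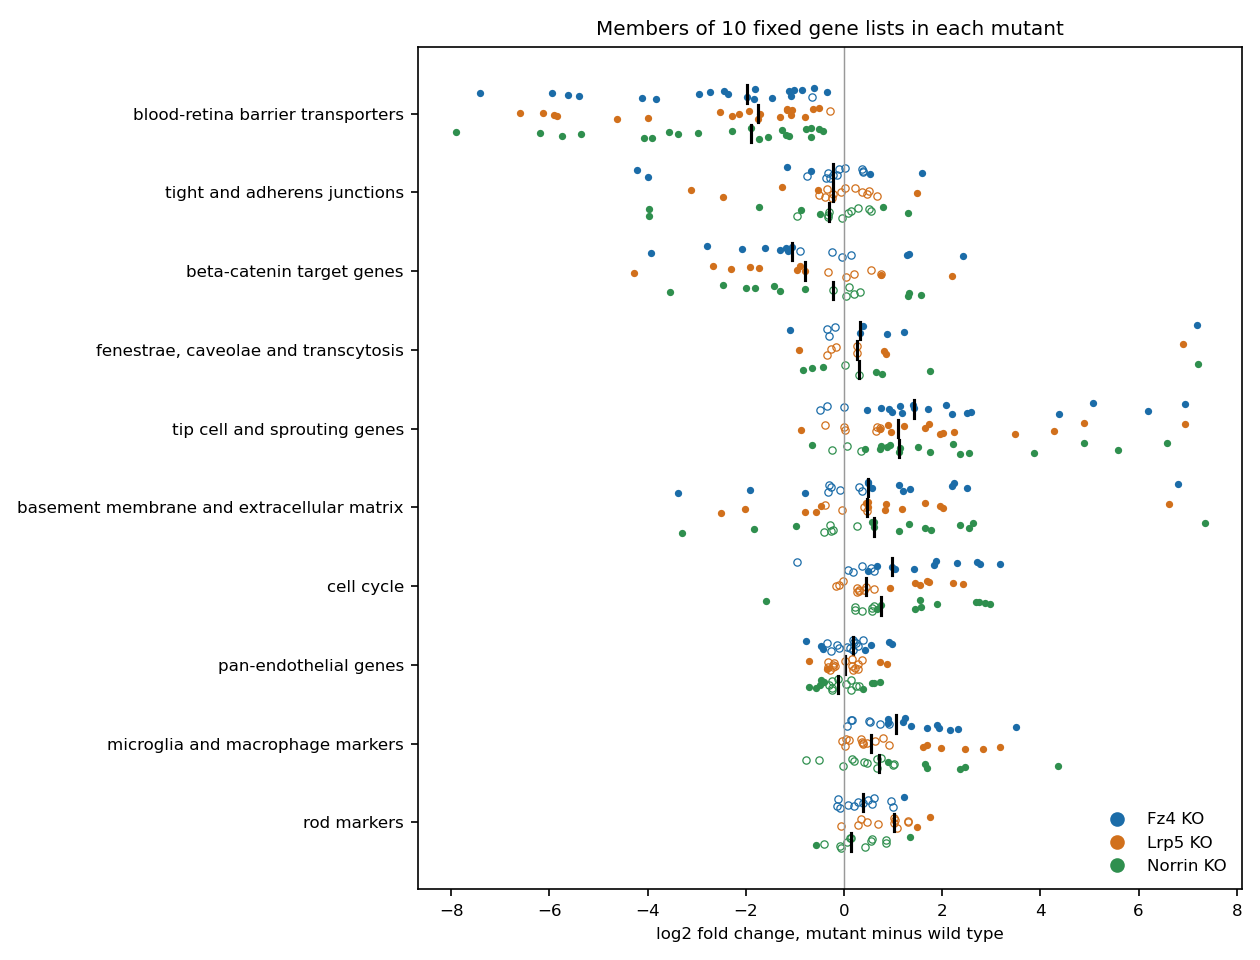
Log2 fold change against wild type of the members of 10 gene lists in each mutant, filled where a member passed an adjusted p of 0.05 and open where not, with black bars for the medians. Barrier transporters have medians of −1.98, −1.74 and −1.90 in Fz4, Lrp5 and Norrin KO, and tip cell genes +1.42, +1.09 and +1.13.

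Basement membrane genes rose more often than they fell: 11 up and 5 down of 19 (12 and 5 over the list alone), median +0.52, camera adjusted p = 0.0172 (adjusted p = 0.518 with an estimated correlation). Besides Col15a1, Nid2 and Lamb1, Col18a1 (+2.17), the source of endostatin, Hspg2 (+1.39), perlecan, and Col5a1 (+1.27) rose. Spock2 (−3.06), a proteoglycan of brain vessels, Fn1 (−1.92), fibronectin, and Agrn (−0.39), agrin of barrier vessels, fell instead. By mutant 10 rose and 3 fell in Fz4 KO (10 and 3 over the list alone, adjusted p = 0.0152), 10 and 5 in Lrp5 KO (10 and 5, adjusted p = 0.0109) and 11 and 3 in Norrin KO (11 and 4, 8 and 6 after centring, adjusted p = 0.0356). The 3 calls were lost, at adjusted p = 0.510, 0.507 and 0.571 with an estimated correlation, and in Norrin KO the call also ended without Norrin KO 3 (adjusted p = 0.0724) or wild type 3 (adjusted p = 0.0646).

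Cell cycle genes rose, 12 of 17 with none down (15 and 1 over the list alone), median +0.85, camera adjusted p = 3.9e-07 (adjusted p = 0.104 with an estimated correlation). Birc5 (+2.86), survivin, Cdk1 (+2.62), the mitotic kinase, Ccnb2 (+2.39), its cyclin, and Mki67 (+1.88 in Fz4 KO), the marker of cycling cells, rose in every mutant. Top2a, a topoisomerase of dividing cells, fell by 1.58 in Norrin KO on the brightest of its probe sets and was +0.20 (adjusted p = 0.372) on the mean of all of them. The list rose in Fz4 KO (11 up and 0 down, 14 and 1 over the list alone, adjusted p = 3.7e-07), Lrp5 KO (7 and 0, 8 and 0, adjusted p = 7.9e-06) and Norrin KO (10 and 1, 12 and 1, adjusted p = 2.1e-05), with adjusted p = 0.104, 0.162 and 0.183 with an estimated correlation.

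Markers of macrophages and microglia were higher in the mutants, 11 of 18 with none lower (13 and 0 over the list alone), median +0.73, camera adjusted p = 4.3e-05 (adjusted p = 0.507 with an estimated correlation). The members that rose furthest were Mrc1 (+3.68), the mannose receptor of perivascular macrophages, the MHC class II genes H2-Ab1 (+2.33) and H2-Aa (+2.28), and Pf4 (+2.00), while the microglial receptor Cx3cr1 (−0.17), the integrin Itgam (−0.02) and the protease Ctss (+0.02) did not pass. Counts were 11 up in Fz4 KO (13 over the list alone, adjusted p = 3.4e-06), 6 in Lrp5 KO (6, adjusted p = 3e-05) and 6 in Norrin KO (7 up and 1 down, adjusted p = 0.0264). With an estimated correlation these were adjusted p = 0.453, 0.507 and 0.704, and without Norrin KO 2 the last was adjusted p = 0.187. Other blood cell markers, 11 measured, had no member past the test in the mean of the mutants (adjusted p = 0.692). Red blood cell markers fell, 2 of 5 (2 over the list alone, adjusted p = 0.0142, adjusted p = 0.204 with an estimated correlation), Alas2 (−1.87) of haem synthesis and the beta-globin Hbb-b2 (−1.59). In Fz4 KO 3 fell (3, adjusted p = 0.00374, adjusted p = 0.162 with an estimated correlation), and in Lrp5 and Norrin KO the list did not pass (adjusted p = 0.0897 and 0.0507).

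Inflammatory genes of endothelium rose together with these macrophage markers: 6 of 18 up and 1 down (8 and 1 over the list alone), median +0.45, camera adjusted p = 0.0176 (adjusted p = 0.606 with an estimated correlation, and adjusted p = 0.875 with the test pointing down once the macrophage mean was a covariate). Selp (+5.01) and Sele (+3.56), the selectins that slow leukocytes, Lrg1 (+4.17), a glycoprotein of remodelling retinal vessels, Ccl7 (+1.81), a monocyte chemokine, and Il6 (+1.32) rose, Vcam1 (−0.67) fell, and Icam1 (+0.07) did not pass. The list rose in Fz4 KO (6 up and 1 down, 9 and 1 over the list alone, adjusted p = 0.00477, adjusted p = 0.524 with an estimated correlation) and in Lrp5 KO (5 and 0, 5 and 0, adjusted p = 0.00039, adjusted p = 0.453 with an estimated correlation) but not in Norrin KO (4 and 2, 5 and 2, adjusted p = 0.568). Interferon response genes did not pass against wild type (3 of 20 up and 3 down, adjusted p = 0.984 over the mutants).

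Genes of arteries and veins moved both ways without passing as lists. Of 15 arterial genes 6 rose and 3 fell (6 and 4 over the list alone, adjusted p = 0.359), Gja5 (+1.22), Unc5b (+1.21) and Gja4 (+0.85) up and the arteriolar marker Gkn3 (−3.70) and the kinase Bmx (−1.44) down. The median was +0.16 and the mean −0.01, and in Lrp5 KO the median of +0.17 stood against a mean of −0.21. Of 11 venous genes 5 rose and 4 fell (5 and 4, adjusted p = 0.814, median −0.14 against a mean of +0.66), with Ackr1 (+3.03), the chemokine receptor of venules, and Nrp2 (+0.92) up beside Selp, and Flrt2 (−1.36) and Tmem252 (−1.15) down. Of the pan-endothelial genes 4 of 19 rose and 6 fell (6 and 7, median +0.03, adjusted p = 1), Emcn (+0.82) and Kdr (+0.80) up, Tek (−0.65) down and Pecam1 not past the test.

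Immediate early genes, which rise when tissue is dissociated, were lower in the mutants: 7 of 20 fell (8 over the list alone, median −0.23, camera adjusted p = 0.00112, adjusted p = 0.373 with an estimated correlation). Klf2 (−0.97), the flow-responsive factor, fell most. Norrin KO, whose arrays had the longest actin 3′ to 5′ gaps, carried most of this (6 down, 10 over the list alone, 14 after centring, adjusted p = 6.6e-05, adjusted p = 0.262 with an estimated correlation), while Fz4 KO had 1 member down (1, adjusted p = 0.0324, adjusted p = 0.510 with an estimated correlation, a call that ended without Fz4 KO 3 or wild type 3, at adjusted p = 0.088 and 0.0646, and with matched arrays as a block, at adjusted p = 0.0523) and Lrp5 KO did not pass (1, 1, adjusted p = 0.0585).

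Markers of retinal neurons and glia were listed to look for other cells of the tissue, and 3 of these lists were higher in Lrp5 KO. Rods rose there (2 of 13, 3 over the list alone, median +1.03, adjusted p = 0.000349, adjusted p = 0.424 with an estimated correlation), led by the transducin Gnat1 (+1.74) and the calcium sensor Rcvrn (+1.48). Cones rose too (4 of 8, 7 over the list alone, median +1.05, adjusted p = 0.000119, adjusted p = 0.199 with an estimated correlation), with the opsin Opn1sw (+1.61), and so did Müller glia (3 of 12, 3 over the list alone, adjusted p = 0.00839, adjusted p = 0.533 with an estimated correlation), with the water channel Aqp4 (+1.53). The last call ended without Lrp5 KO 1 (adjusted p = 0.0854), 1 of the arrays that stood apart. These 3 lists did not pass in Fz4 KO, in Norrin KO or over the mutants (adjusted p = 0.0833, 0.0830 and 0.746 over the mutants). Bipolar, amacrine, horizontal and ganglion cells, astrocytes, pericytes, fibroblasts and pigment cells did not pass against wild type (adjusted p = 0.631, 0.932, 0.692, 0.0897, 0.386, 0.160, 0.492 and 0.932 over the mutants). Nor did lens crystallins or sex-linked genes (adjusted p = 0.646 and 0.998). The sex-linked list joins Xist with Y genes, which move in opposite directions when sex differs, so its result says nothing about sex makeup.

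Of 18194 genes, 2554 were higher and 1803 lower over the mean of the mutants, 1404 of the 4357 by at least 2-fold. The count was 1983 with the macrophage mean as a covariate and 2415 with the replicate number as a block. The arrays of mutants and wild type did not overlap at 8.29% of all genes, where chance gives 0.04%. The share of called genes that were higher, 58.6%, depended on the scale of the arrays: it was 53.8% after quantile normalization again and 43.1% after centring each array on its median, which shifts every fold change by −0.12. All 21 barrier transporters still fell, and 15 tip cell genes rose and 2 fell, after centring.

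Each mutant was then compared with wild type on its own. In Fz4 KO the largest changes were those of the shared profile, with Gpihbp1 (+7.29), Btnl9 (+7.22) and Plvap (+7.19) at the top and Fzd4, Slc38a5 (−7.42) and Car4 (−6.10) at the bottom. Sgpp2 (−4.64), a phosphatase of sphingosine 1-phosphate, also stood among the 10 largest falls. In Lrp5 KO Esm1 (+6.95), Plvap (+6.91) and Aqp1 (+6.76) led, Selp (+5.57) and Cmah (+5.33), a sialic acid hydroxylase, entered the 10 largest rises, and Rad54b (−5.18), a recombination repair gene, the falls. In Norrin KO Col15a1 (+7.34), Btnl9 (+7.31) and Gpihbp1 (+7.30) led, Slc38a5 (−7.90) and Slco1c1 (−6.20) fell most, and Pllp (−4.46), a membrane proteolipid, was added to the falls.

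In Fz4 KO 1940 genes were higher and 1107 lower, in Lrp5 KO 1025 and 1322, and in Norrin KO 3036 and 1661. At least 2-fold were 1549 of 3047, 1058 of 2347 and 2100 of 4697. Arrays of the mutant and of wild type did not overlap at 23.2%, 16.7% and 25.3% of genes against 2.38% by chance. The Fz4 KO count was 1910 without Fz4 KO 3, and the Lrp5 KO count 1517 without Lrp5 KO 1. The macrophage mean as a covariate gave 1276 for Fz4 KO and 2515 for Norrin KO, and the rod mean 1115 for Lrp5 KO. The replicate number as a block gave 1921, 1377 and 2781. For Norrin KO the count was 2744 with Xist and Eif2s3y and 2828 with the 3′ to 5′ gap as covariates. Array weights estimated gene by gene gave 4943 and 4412 genes for Fz4 and Lrp5 KO. The default weights, whose estimation did not converge, gave 5059 and 6435. With the matched arrays as a block the counts were 2578 and 2220, 2230 and 1764 of them called before with the same sign. A correlation fitted within matched arrays gave 4736 and 4167. Centring changed the share of higher genes from 63.7% to 47.6% in Fz4 KO (shift of every gene −0.14), from 43.7% to 53.5% in Lrp5 KO (+0.08) and from 64.6% to 32.4% in Norrin KO (−0.28). After quantile normalization again the shares were 55.4%, 44.7% and 60.6%. The balance of rises and falls thus turned with centring and not with quantile normalization.

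The next question was how far the 3 mutants changed the same genes. Rising with the same sign in all 3 were 817 genes and falling were 560, Plvap, Esm1 and Aqp1 among the former and Slc38a5, Slco1c1 and Car4 among the latter. Another 1274 genes passed in exactly 2 mutants, 526 in Fz4 KO alone, 466 in Lrp5 KO alone and 2414 in Norrin KO alone, of 6059 in any, and 31 had opposite signs between mutants. With array weights 2068 genes were shared by all 3 (gene by gene), or 2339 (default, not converged), and fewer with the macrophage mean (838) or the rod mean (892) as a covariate or the replicate number as a block (896). Fz4 and Lrp5 KO shared 947 higher genes (109 expected) and 801 lower (80.4), Fz4 and Norrin KO 1418 (324) and 726 (101), and Lrp5 and Norrin KO 838 (171) and 648 (121).

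Because the mutants share their wild-type arrays, part of any likeness is built in. Fold changes of Fz4 and Lrp5 KO correlated at r = 0.814, where groups simulated without change gave 0.333, and at 0.720 (0.593 to 0.824) with the wild-type arrays split between them (0.813 when each had its 3 matched arrays and 0.634 when these were crossed), with a covariance of 0.350 against 0.0211 simulated. For Fz4 and Norrin KO r was 0.826 (simulated 0.334, split 0.750, covariance 0.452), and for Lrp5 and Norrin KO 0.663 (simulated 0.332, split 0.582, covariance 0.309). None of the simulations gave a gene shared by all 3 groups. Among 936 genes at least 2-fold higher over the mutants the median rise was 1.63 ± 0.19 in Fz4 KO, 1.16 ± 0.18 in Lrp5 KO and 1.75 ± 0.13 in Norrin KO (SD, n = 3), and among 468 lower genes the median changes were −1.54, −1.51 and −1.51.

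**Figure D4:**
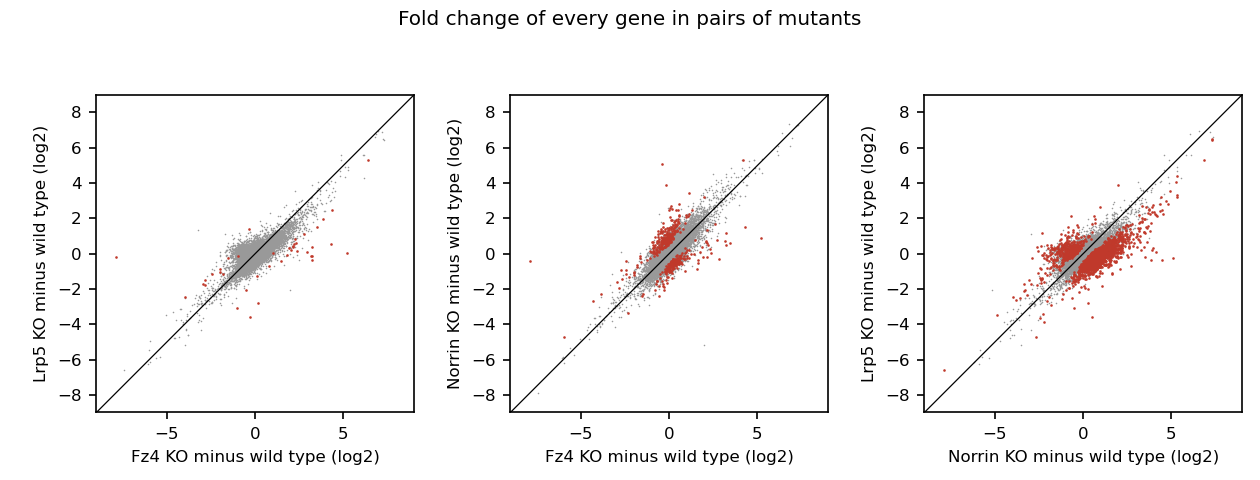
Log2 fold change against wild type of every gene in 1 mutant against another, with the line of equality, in red the genes called between the 2 mutants. Correlations are 0.814, 0.826 and 0.663, with 41, 423 and 2171 genes in red for Fz4 against Lrp5, Fz4 against Norrin and Norrin against Lrp5.

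The last question was where the mutants differ from each other. Fz4 and Lrp5 KO, which lack the receptor and its coreceptor, differed at the fewest genes in the fit without weights or covariates, though not under every setting. Besides the targeted genes, Ifi202b (+5.20), an interferon-inducible gene whose expression varies between mouse strains, Ctse (+3.73), cathepsin E, Glycam1 (+3.60), a ligand of L-selectin on high venules, Map3k7cl (+3.38), a kinase-like gene, and Galc (+3.32), a lysosomal enzyme of myelin lipids, were higher in Fz4 KO. Ifi213 (−1.74), of the same interferon family, Lsr (−1.54), Paqr5 (−1.38), a progestin receptor, and Pcp4l1 (−1.28), a calmodulin-binding protein, were lower, as was Fzd4 (−7.67). The vessel lists differed in degree: tip cell genes were higher in Fz4 KO with 0 members past the test (1 over the list alone, median +0.29, adjusted p = 0.00558) and so were arterial genes, 1 member (2, adjusted p = 0.0130), led by the connexin Gja5 (+1.85). Cell cycle genes were higher as well (0, 0, adjusted p = 0.0224), and barrier transporters (2 down, 4 down and 1 up, adjusted p = 0.0224), junctions (1 down, 2, adjusted p = 0.0395, median +0.02 against a mean of −0.21) and venous genes (0, 0, adjusted p = 0.0126) were lower. All 6 were lost, at adjusted p = 0.393, 0.479, 0.494, 0.487, 0.448 and 0.393 with an estimated correlation. Single arrays ended 5 of them. Without Lrp5 KO 2 the mean of the transporters turned from −0.10 to +0.02 (adjusted p = 0.28), and it was −0.06 without Fz4 KO 2 (adjusted p = 0.0941). Arterial genes were lost without Lrp5 KO 3 (adjusted p = 0.0501), and venous genes without Fz4 KO 2 or Lrp5 KO 2 (adjusted p = 0.0687 and 0.0765). Cell cycle genes were lost without Fz4 KO 2 or Lrp5 KO 2 or 3 (adjusted p = 0.253, 0.0755 and 0.0721). The junction call ended without Fz4 KO 1 or 2, Lrp5 KO 2 or wild type 3 or 4 (adjusted p = 0.0501 to 0.154). With matched arrays as a block the transporter, arterial and cell cycle calls were lost as well (adjusted p = 0.156, 0.374 and 0.236).

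Lists of cell types were lower in Fz4 than in Lrp5 KO for rods, cones, Müller glia, bipolar cells, pigment cells and red blood cells (adjusted p = 0.00287, 0.0124, 0.00556, 0.0224, 0.00287 and 0.00287, with adjusted p = 0.494, 0.479, 0.545, 0.370, 0.393 and 0.370 with an estimated correlation), of whose members only Hbb-b2 (−1.25) passed. Without Fz4 KO 2 rods, cones, Müller glia and bipolar cells were lost (adjusted p = 0.0941, 0.0941, 0.245 and 0.0702), cones also without Lrp5 KO 2 (adjusted p = 0.123) and bipolar cells without Fz4 KO 1 (adjusted p = 0.0531). Without the 3 arrays that stood apart rods, cones and Müller glia were lost too (adjusted p = 0.068, 0.085 and 0.0688), the rod mean moving from −0.48 to −0.28. Bipolar and red blood cells were lost with matched arrays as a block (adjusted p = 0.137 and 0.133). Over all genes 29 were higher and 12 lower, 41 in all, 37 by at least 2-fold, and the count was 11 without Fz4 KO 3, 18 without Lrp5 KO 3, 20 without Fz4 KO 1, 24 without Lrp5 KO 1 and 26 without Lrp5 KO 2. Arrays did not overlap at 16.5% of genes against 10% by chance. The share of higher genes was 70.7%, 56.5% after quantile normalization again and 45.8% after centring (shift −0.21). With Xist and Eif2s3y as covariates the count was 6. Array weights gave 225 (gene by gene) or 1635 (default, not converged). With matched arrays as a block only Fzd4 was called. Lrp5, deleted in Lrp5 KO, was missed, so this fit overlooks true differences. A correlation within matched arrays gave 75 genes.

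Between Fz4 and Norrin KO, receptor and ligand, Ifi202b (+4.29), Lif (+3.14), a cytokine, Tmem87a (+2.87), a Golgi protein, Ctse (+2.75) and Dpys (+2.74), a pyrimidine enzyme, were higher in Fz4 KO. Lower were Fzd4 (−7.43), Ifi44l (−5.45), an interferon-induced gene, Gdpd3 (−4.05), a lysophospholipase, Ccbe1 (−2.60), which activates VEGF-C, and Slc26a7 (−2.53), an anion exchanger. The pathway lists that differed did so by small shifts. TGF-beta and BMP genes were higher in Fz4 KO, 2 of 15 members (5 over the list alone, median +0.25, adjusted p = 0.0124), the target genes Id1 (+1.05) and Id3 (+0.58). Tip cell genes (0, 0, adjusted p = 0.0247), immediate early genes (1, 1, adjusted p = 0.0124), inflammatory genes (1, 2, adjusted p = 0.0152), with the inhibitor Tnfaip3 (+1.12), interferon genes (0, 0, adjusted p = 0.0128) and pan-endothelial genes (0, 0, adjusted p = 0.0298) were higher too. With an estimated correlation these 6 were adjusted p = 0.393, 0.487, 0.494, 0.654, 0.701 and 0.494. All compare arrays with an actin 3′ to 5′ gap of 0.577 to 0.861 with arrays at 1.05 to 2.92, while the Gapdh gap overlapped (0.798 to 1.068 and 0.887 to 2.987). With the gap as a covariate all 6 calls ended (adjusted p = 0.052 to 0.3). The mean of the immediate early genes stayed about as large (+0.20 with the covariate, +0.21 without). The means of the other lists shrank, as for pan-endothelial genes (+0.08 with the covariate, +0.14 without). Interferon calls ended without Fz4 KO 2, Fz4 KO 3 or Norrin KO 1 (adjusted p = 0.0687, 0.226 and 0.0785), and tip cell calls without Fz4 KO 2, Norrin KO 1 or Norrin KO 2 (adjusted p = 0.0786, 0.116 and 0.104). The pan-endothelial call ended without Fz4 KO 1 or 2 or Norrin KO 1 or 2 (adjusted p = 0.0531, 0.0602, 0.18 and 0.0618), and the inflammatory call without Fz4 KO 3 or Norrin KO 3 (adjusted p = 0.111 and 0.0636).

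Of the cell type lists, macrophage (1 member, 1 over the list alone, adjusted p = 0.0255) and Müller glia (0, 0, adjusted p = 0.0124) genes were higher in Fz4 than in Norrin KO and fibroblast (0, 2, adjusted p = 0.0195) and pigment cell genes (1, 6, adjusted p = 0.00287) lower, the melanosome enzyme Tyrp1 by 2.49. With an estimated correlation these were adjusted p = 0.801, 0.616, 0.370 and 0.393. The macrophage call ended without Fz4 KO 2, Fz4 KO 3 or Norrin KO 3 (adjusted p = 0.103, 0.0825 and 0.298) and with the 3′ to 5′ gap as a covariate (adjusted p = 0.249). Müller glia were lost without Fz4 KO 1 or Norrin KO 3 (adjusted p = 0.193 and 0.122), fibroblasts without Norrin KO 2 or 3 (adjusted p = 0.0528 and 0.0874). Over all genes 163 were higher and 260 lower, 423 in all, 199 by at least 2-fold. Arrays did not overlap at 24.6% of genes against 10% by chance. It was 61 without Fz4 KO 1, 97 without Fz4 KO 2, 100 without Fz4 KO 3, 102 without Norrin KO 1, 195 without Norrin KO 3, 217 without wild type 2, 228 without wild type 6 and 764 without Norrin KO 2. The share higher was 38.5%, 35.7% after quantile normalization again and 63.2% after centring (shift +0.15). With the 3′ to 5′ gap as a covariate 18 genes were called, with Xist and Eif2s3y as covariates 7. With array weights it was 993 (gene by gene) or 1092 (default, not converged).

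Norrin and Lrp5 KO differed most. Interferon-inducible Ifi44l (+5.31) and Gbp2b (+4.88), Glycam1 (+4.22), Galc (+4.07) and Vsig4 (+4.03), a complement receptor of resident macrophages, were higher in Norrin KO. Galc was 8.30 ± 0.35 in wild type, 8.77 ± 0.14 in Norrin KO and 4.70 ± 1.13 in Lrp5 KO, while Ifi44l was 7.70 ± 1.49 in Norrin KO and 2.64 ± 0.43 in wild type. Over the mean of the mutants Galc was at −1.13 on this probe set. Its other probe sets were at +0.43 and +0.06 and did not pass. Neurod4 (−3.52) and Isl1 (−2.82), transcription factors of retinal neurons, Csn1s2a (−2.98), a casein, Csf3 (−2.82), a granulocyte cytokine, and Ccdc30 (−2.69), a coiled-coil gene, were lower. Barrier transporters were lower in Norrin than in Lrp5 KO, 5 of 21 lower and 2 higher (5 and 3 over the list alone, median −0.15, adjusted p = 0.0224), Slco1a4 (−1.27) down and the iron exporter Slc40a1 (+1.15) up, and junctions lower (1 down and 1 up, 2 and 2, 7 and 0 after centring, adjusted p = 0.0249), Lsr by 1.52. Inflammatory genes were lower (2, 2, adjusted p = 0.0148), Csf3 and Ptgs2 (−1.47), and so were immediate early genes (1, 1, 7 after centring, adjusted p = 0.0130). All 4 were lost, at adjusted p = 0.487, 0.393, 0.654 and 0.494 with an estimated correlation, and the transporter and junction calls ended without Norrin KO 1 (adjusted p = 0.0785 and 0.0826) or Lrp5 KO 2 (adjusted p = 0.141 and 0.0701). Without Lrp5 KO 2 the mean of the transporters was −0.06 in place of −0.18. With the 3′ to 5′ gap as a covariate the transporter, junction and immediate early calls ended (adjusted p = 0.131, 0.136 and 0.0509), as they did without the 3 arrays that stood apart (adjusted p = 0.051, 0.094 and 0.149). The means of these lists were −0.18, −0.23 and −0.25 with all arrays and no covariate. They were −0.15, −0.16 and −0.24 with the gap and −0.21, −0.18 and −0.17 without those arrays, so the changes did not go away with the calls.

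Fibroblast markers were higher in Norrin than in Lrp5 KO, 5 of 10 (6 over the list alone, median +0.97, adjusted p = 0.0224, adjusted p = 0.370 with an estimated correlation), among them the growth factor receptor Pdgfra (+2.91) and the collagens Col6a1 (+2.37) and Col1a1 (+1.87), a call that ended without Norrin KO 3 (adjusted p = 0.0752) or Lrp5 KO 2 (adjusted p = 0.0584). Müller glia (4, 5, adjusted p = 0.000423), with Aqp4 (−2.39) and Rlbp1 (−2.15), cones (3, 4 down and 1 up over the list alone, adjusted p = 0.00558), with Opn1sw (−1.99), and rods (1, 1, adjusted p = 0.00710) were lower, with adjusted p = 0.487, 0.448 and 0.545 with an estimated correlation. The rod call ended without Norrin KO 3 (adjusted p = 0.27). The astrocyte genes Gfap (+2.73) and S100b (+2.78) ran the other way, with no call for their list (adjusted p = 0.791). Over all genes 1729 were higher and 442 lower, 2171 in all, 1029 by at least 2-fold, and 668 without Lrp5 KO 1, 987 without Lrp5 KO 3, 1036 without Norrin KO 1, 1274 without Norrin KO 3 and 745 without all 3 arrays that stood apart. With the 3′ to 5′ gap as a covariate it was 551, with the rod mean 1370, and with only these 2 groups fitted 198. Weighting the arrays gave 3428 (gene by gene) or 5446 (default, not converged). Arrays did not overlap at 30.8% of genes against 10% by chance. The share higher was 79.6%, 74.0% after quantile normalization again and 24.6% after centring (shift −0.36).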

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

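Of the tests below, those on macrophage and pigment cell markers, on the share of endothelial cells, on genes of like signal and the fits with added covariates or without arrays that stood apart and with matched arrays were chosen after the results were seen. Regroupings of the arrays that ignore the genotype were counted for every number of called genes. Only the real split of 9 arrays gave as many genes as it did (1 of 84 each): 3047 for Fz4 KO with at most 6 in another split, 2347 for Lrp5 KO with at most 1237, and 4697 for Norrin KO with at most 1. Among 100 drawn regroupings of the 15 arrays only the real one (1) reached 4357 genes over the mean of the mutants (highest other 1859), 40 gene lists past the test (34) and 1377 genes shared by the 3 mutants (1). No other regrouping gave as many, but such counts can show no share below 1 of 84 or 1 of 100. For gene lists the highest other count, 34, lay near the real 40. Between mutants the 10 splits of 6 arrays are too few for such a statement, with 41 genes against a highest other of 0 for Fz4 and Lrp5 KO, 423 against 2 for Fz4 and Norrin KO, and 2171 against 1 for Norrin and Lrp5 KO (1 of 10 each).

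The first pattern weighed was the fall of barrier transporters in all mutants with the rise of genes such as Plvap and Gpihbp1. The list of fenestrae and caveolae did not pass camera. The normalization between arrays would move genes of like signal alike. For all 20 named genes the 200 genes nearest in wild-type signal had a median change of less than 2% of theirs. This speaks against the normalization as the source for these 20 only, as they were picked for the largest changes. All 21 transporters fell on the deposited scale, after quantile normalization again and after centring. A lower share of endothelial cells would lower the genes of all endothelium too, but all 19 pan-endothelial genes measured lay above the mean change of the transporters (−2.64) by more than 2 standard errors. Endothelium of the choroid, whose capillaries are fenestrated, stays open in all 3 mutants: of 12 pigment cell markers 0 were higher in Fz4 KO, 1 in Lrp5 KO and 4 in Norrin KO (Tyrp1 +2.47, Dct +2.52), but the antibody to PECAM could keep such endothelium without its pigment cells. The genotype named by the design remains an open explanation. The transporter list and the test were written down before the data were examined, whereas genes such as Gpihbp1 were named for the size of their change.

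The second pattern was the difference between Norrin and Lrp5 KO, 2171 genes and 8 gene lists by a test of the difference itself. With the sex-linked genes Xist and Eif2s3y as covariates 1366 of these genes were called again with the same sign, which argues against the sex makeup of the pools as the whole source. Without the 3 arrays that stood apart 613 were called again, and with the gap between 3′ and 5′ controls as a covariate 433. Both numbers lie between the bounds set for these tests and leave the explanations open. For genes that stand out in Norrin KO, genotype and processing of these pools cannot be told apart, since no other arrays matched these 3. Some differences came from the Lrp5 KO arrays instead, as for Lrp5 itself (4.91 in Lrp5 KO, 7.95 in Norrin KO and 7.69 in wild type).

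The third pattern was the higher signal of macrophage markers in the mutants. After the list mean of each array was taken away 15 of 18 members still differed, but members with other baselines or other sources would differ too, so a larger share of macrophages stays open. A lower share of endothelial cells would raise the markers of every other cell type. Of the 13 other lists 10 lay below the macrophage mean of +1.07 by more than 2 standard errors. Rods, cones and ganglion cells (+0.54, +0.52 and +0.68) did not. The ganglion list holds Thy1, also known from activated endothelium, and its median was only +0.29. The macrophage list was taken up because it rose most, so others lying below it cannot decide the question, and this explanation stays open. A change in the kind of macrophage beside the vessels, or the genotype acting on these cells, could also underlie the rise and stays open, since no cells other than the purified fraction were measured.

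Other results were flagged because groups differed by a test of the difference or because 1 array lay far from the rest of its group. Fz4 and Lrp5 KO differed at 41 genes and 12 gene lists (1 gene with matched arrays as a block, which missed the deleted Lrp5), and Fz4 and Norrin KO at 423 genes and 10 lists. Among the wild-type arrays, the gap of the most distant array as a share of the range was 0.642 for the mean of the junction list (wild type 5, low), 0.695 for arterial genes (wild type 4, low), 0.868 for immediate early genes (wild type 1, low) and 0.764 for astrocyte genes (wild type 1, high). For single genes it was 0.653 for Gpihbp1 (wild type 2), 0.756 for Pglyrp1 (wild type 5), 0.778 for Ifi44l and 0.694 for Gdpd3 (both wild type 2) and 0.642 for Ndp (wild type 4). These are 9 of 85 tested groups of values, where about 1 in 20 (4.25) is flagged by chance.

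A signal was also seen in probe sets outside the gene counts. Of 10092 probe sets without exactly 1 gene symbol, the 51 controls left out, 688 passed in Fz4 KO, 380 in Lrp5 KO, 1523 in Norrin KO and 1081 over the mean of the mutants, with a largest change of −7.21 in the last.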

How the results depend on the processing

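Chosen after the results were seen were the fits with array weights estimated gene by gene, those with matched arrays, those without the 3 arrays that stood apart and those with Xist and Eif2s3y, the macrophage mean or the 3′ to 5′ gap as covariates. Over 794 results for named genes and list members, 19735 of 21637 values kept direction and side of the threshold, 1896 were no longer past it and 6 reversed. Over 238 results for gene lists 7064 of 7539 did, 283 fell short, 189 newly passed and 3 reversed. Signal near background limits the array, as for Ndp, and only genes above the median gene gave 27 and 700 calls for Fz4 against Lrp5 KO and against Norrin KO, and correlations of 0.913, 0.844 and 0.761. Unless said, the cause of a change was not tested.

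Leaving out 1 array gave 1910 to 3355 genes for Fz4 KO, 1517 to 2663 for Lrp5 KO, 3383 to 4980 for Norrin KO, 3737 to 4525 for the mean of the mutants, 11 to 54 for Fz4 against Lrp5 KO, 61 to 764 for Fz4 against Norrin KO, 668 to 2836 for Norrin against Lrp5 KO, 1049 to 1472 shared genes and 37 to 44 gene lists. Fold changes of the targeted genes were −8.04 to −7.75 (Fzd4), −2.95 to −2.53 (Lrp5) and −0.42 to −0.18 (Ndp), and correlations 0.718 to 0.879 (Fz4 and Lrp5), 0.781 to 0.836 (Fz4 and Norrin) and 0.551 to 0.740 (Lrp5 and Norrin).

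Quantile normalization again gave 658 genes for Fz4 against Norrin KO, the mean of all probe sets 275, and eBayes with trend and robust 642. Each probe set on its own, which tests more items, gave 5385 (Fz4 KO), 9265 (Norrin KO), 7978 (mean), 63 (Fz4 against Lrp5), 3361 (Norrin against Lrp5) and 2196 shared. Array weights gave 5059 (Fz4 KO), 6435 (Lrp5 KO), 1635, 1092 and 5446 between mutants and 2339 shared, but the estimation of these weights stopped before it converged, with Lrp5 KO 3 at a weight of 7.65, so these counts are not reliable. Estimated gene by gene, where that array had a weight of 3.19, the weights gave 4943 (Fz4 KO), 4412 (Lrp5 KO), 225, 993 and 3428 between mutants and 2068 shared. With only the groups compared, and so fewer arrays, 5, 19 and 198 genes were called between mutants. At least 2-fold were 1549, 1058, 2100 and 1404 against wild type, 199 and 1029 for Norrin KO against Fz4 and Lrp5 KO, and 705 shared, by construction. The rod mean as a covariate gave 1115 (Lrp5 KO), 1370 (Norrin against Lrp5) and 892 shared. Without the 3 arrays that stood apart 745 genes were called for Norrin against Lrp5 KO. Xist and Eif2s3y as covariates gave 2744 (Norrin KO), 6 and 7 (Fz4 against Lrp5 and Norrin KO), the macrophage mean 1276 (Fz4 KO), 2515 (Norrin KO), 1983 (mean) and 838 shared, and the 3′ to 5′ gap 2828 (Norrin KO), 18 (Fz4 against Norrin) and 551 (Norrin against Lrp5). Of 70 calls of gene lists over the 7 contrasts 13 ended with the 3′ to 5′ gap as a covariate and 19 without the 3 arrays that stood apart (Lrp5 KO 1, Norrin KO 1 and wild type 4). An estimated correlation left 8 gene lists past the test and fry gave 73. Splitting the wild-type arrays gave correlations of 0.720, 0.750 and 0.582, where the pairs share no control and each mutant has 3 controls in place of 6.

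Reversed were Xaf1 (Fz4 KO 2.07, Norrin KO 1.69, mean 1.21) and Top2a (Norrin KO 0.20) with the mean of all probe sets, interferon genes in Fz4 against Lrp5 KO with the array weights that did not converge (−0.21), inflammatory genes (mean 0.26, adjusted p = 0.875, test downwards) and Ccl7 (Fz4 KO −0.53, mean −0.56) with the macrophage covariate, and TGF-beta genes in Norrin KO with fry (0.42, adjusted p = 0.00104).

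The labels number the replicates without saying that a number was shared. Of 9 pairs of a mutant and a wild-type array with the same number 4 correlated over 0.1 (−0.125 to 0.381), of 9 pairs of 2 mutants 1 did (−0.238 to 0.157), and 2 of 9 mutant arrays correlated best with the wild-type array of their number. With a replicate block the counts were 1921 (Fz4 KO), 1377 (Lrp5 KO), 2781 (Norrin KO), 2415 (mean), 19 (Fz4 against Lrp5), 61 (Fz4 against Norrin) and 896 shared. Matching by spike controls and sex genes instead (Lrp5 KO 1 to 3 with wild type 4 to 6) gave 1 gene for Fz4 against Lrp5 KO as a block, which cannot be fitted for Norrin KO, and 4736 (Fz4 KO), 4167 (Lrp5 KO) and 75 (Fz4 against Lrp5) with a fitted correlation of 0.482. That block missed the deleted Lrp5, so few calls there do not show that few genes differ.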

Other observations

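The tests of gene families and of slopes were chosen after the results were seen. Collagens stood out among 27 families grouped by name. Over the mean of the mutants 19 of 42 collagen genes were higher (45.2%, against 14.0% of other genes, odds ratio 5.09, adjusted p = 5.5e-05 over 54 tests), among them the network collagen Col15a1 and, from the list of fibroblast markers, Col6a1 (+2.47) and Col6a2 (+2.49) of collagen VI. Zinc finger genes named Zfp went the other way, with 55 of 336 lower (16.4% against 9.79%, adjusted p = 0.00361). Centring the arrays left 16 collagens higher and 1 lower, and 17 Zfp genes higher and 88 lower. Of 77 potassium channel genes, auxiliary subunits among them, 0 were lower (adjusted p = 0.01), and after centring 2 were lower (2.60% against 14.8% of other genes, adjusted p = 0.0134).

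Growth factor and hypoxia genes moved in both directions. Vegfa (+1.05), the main endothelial growth factor, and Egln3 (+1.66), an oxygen sensor, were higher over the mutants, and Ankrd37 (−1.72) and Bnip3 (−0.77), targets of hypoxia-inducible factor, lower, 5 up and 7 down of 19 (6 and 7 over the list alone) with no call for the list (adjusted p = 0.898). In the TGF-beta and BMP list Bmp6 (+3.30), Tgfbi (+3.00), Tgfb1 (+1.72) and Bmp4 (+1.68) rose and the receptor Acvrl1 (−0.94) fell. The list passed camera in Fz4 KO (5 up and 1 down of 15, 5 and 1 over the list alone, adjusted p = 0.0298) and Lrp5 KO (4 and 0, 4 and 1, adjusted p = 0.0134), with adjusted p = 0.262 and 0.204 with an estimated correlation. With the 3′ to 5′ gap as a covariate the Fz4 KO call ended (adjusted p = 0.0689), though the list mean hardly moved, from +0.75 to +0.73. The list did not pass in Norrin KO (4 and 4, 4 and 7, adjusted p = 0.980), where Id1 (−0.98), Id2 (−1.14) and Id3 (−0.47) were lower. Of 12 Notch genes 6 rose and 1 fell (3 and 1 after centring) without a call by camera (adjusted p = 0.154), Dll1 (+1.14) and Heyl (+1.06) up and Hes1 (−0.62) down. Thy1 (+4.27), listed for ganglion cells but known from activated endothelium, and Igf1 (+2.67), listed for fibroblasts, rose in all mutants while neither list passed.

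A weaker form of the same change in Lrp5 KO was tested as a hypothesis, by the slope of each mutant array on the change in Fz4 KO. For 1046 genes at least 2-fold higher in Fz4 KO the slope was 0.724 ± 0.0861 in Lrp5 KO and 0.965 ± 0.0300 in Norrin KO (SD, n = 3), a difference of 0.2408 ± 0.0527 (SE), as the hypothesis predicts. It was 0.0861 ± 0.0232 after centring and 0.0947 ± 0.0144 with an intercept, so the size of the difference depends on the scaling. For 503 lower genes the difference was 0.007951 ± 0.0412, but 0.153 ± 0.0234 after centring, which leaves the hypothesis open for falling genes.

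Genes close to each targeted gene could carry the chromosome of the strain in which it was targeted. Among the 106 tested genes beside Lrp5, 22 were called between Lrp5 KO and another mutant (20.8%, against 12.0% of other genes, odds ratio 1.92, one-sided Fisher's exact p = 0.00722), as this hypothesis predicts. Beside Fzd4 7 of 200 were called (3.5% against 2.47%, Fisher's exact p = 0.231), which leaves it open. Beside Ndp 20 of 176 were called (11.4% against 12.5%, Fisher's exact p = 0.702), so no excess was seen there. The counts beside Lrp5 and Ndp both include the 2171 calls of Norrin against Lrp5 KO. Processing of the Norrin KO pools could have added to these across the genome and hidden a small excess, so the hypothesis stays open for Ndp too.

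The labelled-cRNA controls and the sex-linked genes varied alike in some groups that the labels do not join, though not always in the same order. BioB was 11.061, 11.149 and 10.279 in Fz4 KO 1 to 3 and 11.684, 11.415 and 10.619 in wild type 1 to 3, and 12.121, 11.025 and 11.283 in Lrp5 KO 1 to 3 and 12.309, 11.2 and 11.494 in wild type 4 to 6. Eif2s3y was 9.566, 9.625 and 3.253 in Fz4 KO and 9.414, 9.783 and 2.692 in wild type 1 to 3, and 10.109, 10.481 and 3.212 in Lrp5 KO and 10.285, 10.218 and 2.806 in wild type 4 to 6. The Cre control was 14.1 to 14.2 on the Norrin KO arrays and 14.4 to 14.7 on all others. Matched by these signals, Fz4 KO 1 to 3 with wild type 1 to 3 and Lrp5 KO 1 to 3 with wild type 4 to 6, arrays correlated in their deviations at 0.276 to 0.653. Of 51 control probe sets, 13 passed in Norrin KO, 2 between Norrin and Lrp5 KO and 1 between Fz4 and Norrin KO.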
